A study of Mus musculus with 6 samples.

How the data were processed

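RNA was measured in 6 libraries of laser-captured CD68-positive cells from aortic root plaques of Ldlr-/- mice aged 20 weeks, 3 from NET-positive and 3 from NET-negative areas. Per the labels' protocols, RNA was isolated with a kit for small samples, treated with DNase and amplified with a low-input kit before Illumina library preparation. The deposited table holds raw counts per gene and library, which the authors made with STAR and Subread on the mouse build mm10, per the submitters' processing notes. The versions, annotation, strand setting and treatment of reads with several matches are not given in the sources used here. Genes that share reads with near-identical copies, or that overlap another gene, are therefore uncertain, haemoglobin genes and antisense partners among them. Groups and pairs were taken from the sample titles. The titles give each NET-positive and 1 NET-negative library the same code, and do not say that a code is an animal, nor how many animals were used. The p-values of single genes measure the spread between these samples, and are too small if captures of different codes came from 1 animal. How NETs were detected in the sections is not given in the sources used here.

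Gene symbols were matched to the Ensembl gene identifiers through GENCODE mouse release M21 and its gene positions in GRCm38, of which mm10 is the other name, and 54079 of the 54146 identifiers had a symbol. Coordinates are given from that annotation. Total counts ran from 27247261 to 37613102, so that a count of 0 allows up to 3 counts, or 0.081 to 0.0989 CPM. Such limits cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

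Counts were tested with edgeR 4.0.16 in R 4.3.3, by glmQLFit and glmQLFTest with TMM normalization, the filterByExpr filter by group, the pair code as a block and Benjamini-Hochberg adjustment, at a threshold of 0.05. This left 2 residual degrees of freedom, and the common biological coefficient of variation was 0.751. Its median fell with abundance, from 1.05 in genes with a mean count under 50 to 0.815 from 50, 0.392 from 500 and 0.251 from 5000 counts. Fold changes are NET-positive over NET-negative on the log2 scale, with standard errors from the fold change and the F statistic, and CPM values are TMM-normalised. Gene lists, 38 in number and fixed from textbook knowledge, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with the correlation preset at 0.01, where at least 5 members were measured, which left out the adipocyte list. Each list was also tested with an estimated correlation and with fry. With the preset correlation camera compares the genes of a list with the other genes. Its p-values therefore do not measure the spread between pairs alone.

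Lists, tests and the rule for named genes were chosen before the data were examined. Where fewer than 5 genes passed in a direction, the rule took the 8 genes of that direction with the smallest p among those that went the same way in all 3 pairs, leaving out unnamed gene models and pseudogenes. It added up to 4 members of each described list with the smallest p, and 15 genes given whatever their values (Cd68, Ldlr, Adgre1, Il1b, Tnf, Nlrp3, Ccl2, Mrc1, Arg1, S100a8, S100a9, Padi4, Mpo, Abca1 and Acta2).

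Alternatives were the fit without the block, median-of-ratios size factors, library size alone, no filter on low counts, a mean count of at least 50, a correction for gene length, robust estimation, DESeq2 1.42.0, limma-voom, an adjusted p under 0.1, a prior count of 5, and fits without each pair or each library. The fits without a single library also left out the block. A mean count of at least 500, and the estimated correlation and fry without pair 2, were added after seeing the data. The procedures were tested on simulated data, 5 draws of counts for the 18480 tested genes with 200 genes changed in each. Counts were drawn from edgeR's fitted means and dispersions, with the fitted group difference taken out before genes were changed. Genes were drawn independently of one another. A list of 16 genes lowered by 2-fold was called by camera with the preset correlation in 5 of 5 draws, with an estimated correlation in 0 and by fry in 1, and camera called 0 of 180 unchanged lists. In the measured libraries the estimated correlation within a list reached 0.8, for cardiomyocyte markers. The 0 of 180 therefore does not give camera's rate of false calls there.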

Results

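The transcriptome of CD68-positive cells was measured in aortic root plaques of 20-week-old Ldlr-/- mice, which lack the low-density lipoprotein receptor and develop atherosclerosis. Cells were cut out of tissue sections with a laser from areas with and without neutrophil extracellular traps (NETs), the webs of DNA and granule proteins that neutrophils release. Amplified RNA from 3 NET-positive and 3 NET-negative captures was sequenced, and each NET-positive library shared a code with 1 NET-negative library, giving 3 pairs. Total counts per library ran from 27247261 to 37613102. The libraries of pair 2 had the fewest detected genes, 21652 in the NET-negative and 22018 in the NET-positive library, against 23597 to 26176 in the other 4. The 2 mitochondrial ribosomal RNA genes took 17.4% to 21.2% of all counts. Between any 2 libraries the correlation of log2 CPM (counts scaled to a common library total) across genes lay between 0.775 and 0.88, and genes are not independent replicates. Capture was on CD68, so the level of Cd68 between areas is no finding: it was 849 ± 207 CPM in NET-positive and 798 ± 279 CPM in NET-negative areas (mean ± SD, n = 3 each). Fibroblast and matrix genes had a mean of 8.415 to 9.525 log2 CPM per library, and macrophage identity genes one of 7.279 to 8.098. A change in a gene or list therefore cannot be assigned to CD68-positive cells alone. Ldlr, knocked out in every mouse, had 3 to 138 counts per library and cannot check the group labels.

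The comparison asked which genes differ between macrophage-rich areas with and without NETs. The gene with the smallest p was F5, coagulation factor V, at 195 ± 116 CPM in NET-positive and 15.1 ± 7.4 CPM in NET-negative areas (mean ± SD, n = 3), a log2 fold change of 3.65 ± 0.395 (SE) that was higher in each pair. The immediate early genes Dusp1, a phosphatase that switches off MAP kinases, and Fos, a subunit of the AP-1 transcription factor, were higher in each pair as well, by 1.12 ± 0.172 and 1.27 ± 0.261 log2 units, with ranges of 0.52 to 1.65 and 0.58 to 2.13 over the fits without a pair or a library. Eng, the endothelial co-receptor endoglin, and Ptprb, an endothelial tyrosine phosphatase, were lower in each pair, by log2 fold changes of -1.26 ± 0.21 and -1.21 ± 0.248. None of these differences passed the test over all genes.

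Of 18480 genes tested with edgeR's quasi-likelihood test with the pair as a block, 0 were higher and 0 were lower at an adjusted p under 0.05, and the lowest adjusted p was 0.998. With the same test it was 0.271 without a filter on low counts and 0.0715 at a mean count of at least 500, which left 7379 genes. At an unadjusted p under 0.05 there were 594 genes, 265 higher and 329 lower in NET-positive areas, where 924 would be expected by chance. The limma-voom test also called 0 genes, with 846 at an unadjusted p under 0.05. The DESeq2 Wald test called 41 genes higher and 92 lower, with 1637 at an unadjusted p under 0.05. Its calls held 15 of the 16 genes named first by the smallest p, Ncf1 being the exception. Those 16 were picked by edgeR's p in the same libraries, so the overlap is no independent check. All 3 pairs went the same way in 25.8% of genes, against 25% by chance. In simulated counts of the same genes, edgeR recovered 1.19% of the genes changed by 2-fold, 21.8% of those changed by 4-fold and 45.8% of those changed by 8-fold, and DESeq2 10.7%, 41.2% and 64.8%. In the same simulation 15.6% of edgeR's calls and 65.6% of DESeq2's calls were genes that had not been changed. These percentages depend on the 200 genes changed per draw and on the spread fitted by edgeR, from which the counts were drawn. They do not give the share of false calls in the measured libraries.

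The other genes with the smallest p among those higher in all 3 pairs, none past the threshold, were Strip1, Gsto1, Tiam2, Ncf1 and Mrvi1. Ncf1 encodes p47phox, a subunit of the phagocyte NADPH oxidase, and stood at 80.1 ± 21.8 CPM against 33.2 ± 3.36 CPM (mean ± SD, n = 3), a log2 fold change of 1.23 ± 0.28 (SE). Gsto1, a glutathione transferase, stood at 36.1 ± 6.59 against 10.3 ± 3.78 CPM, and Strip1 at 32.6 ± 11.2 against 8.26 ± 2.4 CPM. Tiam2, a Rac exchange factor, and Mrvi1 had log2 fold changes of 1.60 ± 0.353 and 2.17 ± 0.496. Lower in all 3 pairs were Bmp2, a bone morphogenetic protein, at -3.04 ± 0.546, Slc16a2, a thyroid hormone transporter, at -1.56 ± 0.297, Plcb2, a phospholipase C, at -1.48 ± 0.296, and Sertad4 at -1.37 ± 0.269. Over the fits without a pair or a library Bmp2 ranged from -3.77 to -1.85, Apcdd1 from -6.99 to -3.95 and Sertad4 from -2.09 to -0.70. Ffar4, a receptor for long-chain fatty acids, and Apcdd1, a Wnt inhibitor, had the largest negative values of this set, -6.73 ± 0.912 and -5.46 ± 1.07, at low levels. Ffar4 reached 70.3 CPM in the NET-negative library of pair 2 and at most 1.74 CPM in the other 5 libraries, and its value ranged from -12.64 to -1.91 over the fits without a pair or a library. In the mouse assembly GRCm38, F5 lies on chromosome 1 from 164151838 to 164220277 on the plus strand, Dusp1 on chromosome 17 from 26505590 to 26562128 on the minus strand, and Eng on chromosome 2 from 32646595 to 32682669 on the plus strand, all annotated as protein-coding. The summed counts of the genes on either side of F5, Selp and Slc19a2, were 0.846, 0.0893 and 0.308 of the F5 count in the NET-positive libraries of pairs 1, 2 and 3, and 8.17, 7.03 and 2.7 of it in the NET-negative ones.

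**Figure D1:**
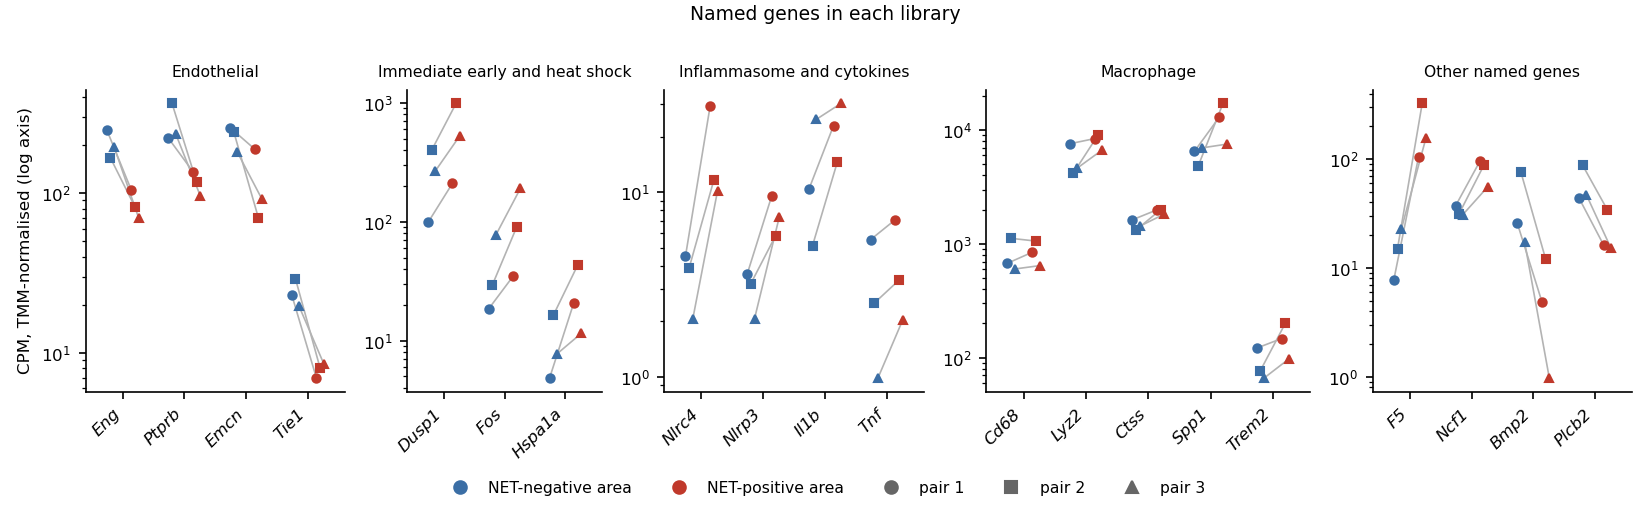
TMM-normalised CPM on log axes of named genes in the 3 NET-negative (blue) and 3 NET-positive (red) libraries, with a line joining the libraries of a pair and the marker shape giving the pair. F5 lies between 7.77 and 22.6 CPM in NET-negative and between 104 and 325 CPM in NET-positive libraries. The endothelial genes lie lower in each NET-positive library than in the NET-negative library of its pair. For Emcn the groups overlap. No gene shown passed the edgeR test over all genes.

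Markers of endothelial cells were lower as a group in the NET-positive captures. The list fell with a median log2 fold change of -1.05 over 16 measured members, and 10 of them were lower in all 3 pairs while 0 were higher in all 3. Eng stood at 85.4 ± 17.7 CPM in NET-positive and 204 ± 42.4 CPM in NET-negative areas, Ptprb at 116 ± 20.2 and 273 ± 79 CPM, Emcn, the sialoglycoprotein endomucin, at 116 ± 63.2 and 226 ± 40.8 CPM, and Tie1, an endothelial receptor kinase, at 7.84 ± 0.799 and 23.9 ± 4.86 CPM (mean ± SD, n = 3). The medians of the single pairs were -0.62, -0.93 and -1.10. With camera and a preset correlation of 0.01 between genes the adjusted p was 7.89e-05 over 37 lists, the 1 list past the threshold. The call was lost in other tests, with an adjusted p = 0.971 with an estimated correlation and an adjusted p = 0.213 with fry. In the simulated data these tests called a list of 16 genes lowered by 2-fold in 0 and 1 of 5 draws. Their loss of the call therefore cannot decide whether the list differs. Adjusted over the list alone 2 members passed, Eng and Ptprb, against 0 over all genes. Such an adjustment within a list does not allow for the 37 lists tried. Several lists of other cell types also had medians below 0 in these captures without passing. Dendritic cell markers had a median of -0.30, with -0.57, -0.10 and -0.84 in the 3 pairs (camera adjusted p = 0.519), and erythroid and platelet markers one of -1.28, with 0.12, -0.40 and -1.29 in the pairs (adjusted p = 0.291), their mean log2 CPM in pair 1 being 2.982 in the NET-positive and 3.155 in the NET-negative library. T and NK cell markers had a median of -0.20 (adjusted p = 0.761), and B and plasma cell markers one of -1.89 over 6 genes, with -2.25, -3.82 and 7.07 in the pairs (adjusted p = 0.867, and 0.0344 as lower without pair 3, both by camera with the preset correlation). Over the 3 pairs the correlation estimated for these 6 genes was 0.314. The adjusted p was 0.999 by camera with that correlation and 0.961 with fry. Haemoglobin genes took 0.0337%, 0.000186% and 0.0304% of counts in the NET-positive libraries of pairs 1, 2 and 3, against 0.0344%, 0.0029% and 0.0746% in their NET-negative partners.

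Markers of the other wall cells differed in direction between pairs. Smooth muscle markers had a median log2 fold change of 0.06, with medians of 0.79, -1.28 and 0.87 in the 3 pairs and a camera adjusted p of 0.761. Myocd, a coactivator of smooth muscle genes, was at 28.7 ± 3.47 against 7.98 ± 6.09 CPM, and Acta2, smooth muscle actin, at 409 ± 312 against 341 ± 173 CPM (mean ± SD, n = 3). Fibroblast and matrix genes had a median of 0.01 and a mean of -0.09, with medians of 0.32, 0.27 and -0.44 in the pairs and an adjusted p of 0.998. In this list Fn1, fibronectin, was higher in each pair, by 0.44 ± 0.111 log2 units, and Postn, periostin, was lower in each pair, at -0.95 ± 0.363, and neither passed the test.

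Lists of the early stress response, of macrophages and of the lysosome had medians above 0 in NET-positive areas and did not pass the threshold. The lysosome list went the other way in pair 2, by its median, with 0.31, -0.11 and 0.27 in the 3 pairs, while its mean log2 CPM there was 8.092 in the NET-positive and 8.05 in the NET-negative library. Immediate early and heat shock genes had a median log2 fold change of 0.33 over 20 members, 7 of them higher and 0 lower in all 3 pairs (camera adjusted p = 0.0903). Dusp1 and Fos passed when adjusted over the list alone, 2 members against 0 over all genes. That adjustment does not allow for the 37 lists tried. Hspa1a, an inducible chaperone, stood at 25.1 ± 16.1 against 9.6 ± 5.94 CPM (mean ± SD, n = 3). The macrophage identity list had a median of 0.21 with 7 of 20 members higher and 0 lower in all 3 pairs (adjusted p = 0.13). Lyz2, lysozyme, stood at 8063 ± 1260 against 5461 ± 1830 CPM, Itgam, the integrin CD11b, at 173 ± 56.1 against 102 ± 6.1 CPM, and Cd14, the endotoxin co-receptor, at 98.8 ± 52.1 against 59.6 ± 47.9 CPM, while Adgre1, the antigen F4/80, stood at 101 ± 32.6 against 91.2 ± 37.8 CPM. The lysosome list had a median of 0.22 with 10 of 28 members higher and 0 lower in all 3 pairs (adjusted p = 0.183), among them the cathepsins Ctss, Ctsb and Ctsl at log2 fold changes of 0.42 ± 0.146, 0.38 ± 0.14 and 0.39 ± 0.146 (SE) and the proton pump subunit Atp6v1a at 0.41 ± 0.173. In these captures the endothelial markers were lower, with the median of -1.05 given above. Without pair 2, the libraries with the fewest detected genes, 4 lists passed the camera threshold with the preset correlation as higher (immediate early and heat shock, lysosome, smooth muscle and cardiomyocyte) and 1 as lower (endothelial). All 5 calls were lost there with an estimated correlation (adjusted p = 0.952) and with fry (lowest adjusted p = 0.218), tests with 1 residual degree of freedom.

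Inflammatory genes went in both directions. The list of inflammatory cytokines and NF-kB targets had a median log2 fold change of 0.15 over 19 members, 6 higher and 1 lower in all 3 pairs (camera adjusted p = 0.742). Il1b, interleukin 1 beta, stood at 22.6 ± 7.9 CPM in NET-positive and 13.4 ± 10.2 CPM in NET-negative areas and was higher in each pair (log2 fold change 0.98 ± 0.485). Tnf, at 4.15 ± 2.63 against 3.01 ± 2.32 CPM, Tnfaip3, a feedback inhibitor of NF-kB, at 92 ± 19.2 against 60.6 ± 10.1 CPM, and Nfkbiz, an inducible NF-kB cofactor, at 102 ± 0.648 against 77.1 ± 18.4 CPM, were higher in each pair too. Il6, interleukin 6, named after its value was seen, was the 1 member lower in each pair, at 7.7 ± 3.16 against 16 ± 6.86 CPM (-1.01 ± 0.621). None of these 5 genes passed over all genes, nor did any list member adjusted over the list alone.

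In the list of inflammasome and pyroptosis genes, single sensors differed in direction. Nlrc4, which acts with NAIP receptors of bacterial proteins, was higher in each pair (17 ± 10.7 against 3.48 ± 1.26 CPM, log2 fold change 2.20 ± 0.603), as was Nlrp3, the sensor that drives interleukin 1 beta processing (7.57 ± 1.91 against 2.95 ± 0.792 CPM, 1.37 ± 0.755). Nlrp1b was lower in each pair (11.6 ± 3.42 against 32.4 ± 17.9 CPM, -1.39 ± 0.414). The list median was -0.17 and its mean 0.02, which differ in sign, with 3 of 14 members higher and 3 lower in all 3 pairs and a camera adjusted p of 0.998. Chemokines had a median of -0.25 over 15 members, 2 higher and 1 lower in all 3 pairs (adjusted p = 0.761). Ccl6 was lower in each pair at -1.10 ± 0.435, Ccl22 and Cxcl16 were higher in each pair at 2.80 ± 2.14 and 0.21 ± 0.185, Cxcl2, a neutrophil attractant, was at 2.62 ± 1.73, and Ccl2, the monocyte attractant, at -0.39 ± 0.509. Interferon-stimulated genes had a median of -0.21 over 23 members, 0 higher and 3 lower in all 3 pairs (adjusted p = 0.274), and the medians of the pairs were -1.11, -0.04 and 0.24, with means of the opposite sign in pairs 2 (mean log2 CPM of 2.709 in the NET-positive and 2.406 in the NET-negative library) and 3 (2.445 and 2.709). Rtp4 and Ifit1 had the smallest p in that list, at 1.43 ± 1.89 against 6.26 ± 5.91 CPM and 0.676 ± 0.357 against 5.88 ± 6.37 CPM. None of these genes or lists passed the threshold in the fit over 3 pairs. With the preset correlation the interferon-stimulated list passed it without the block and the NET-positive library of pair 2.

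**Figure D2:**
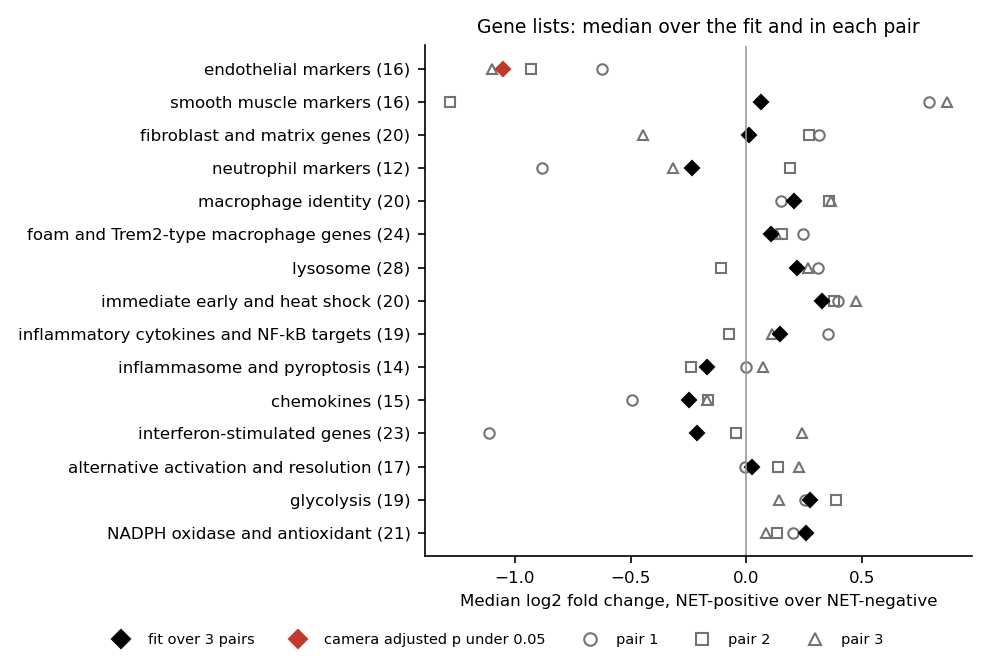
Median log2 fold change of NET-positive over NET-negative areas for 15 gene lists, with the number of measured members in brackets; filled diamonds are the fit over 3 pairs (red where the camera adjusted p is under 0.05) and open symbols are the single pairs. The endothelial list lies at -1.05 with the 3 pairs between -1.10 and -0.62, and the smooth muscle list has 1 pair at -1.28 and the others at 0.79 and 0.87.

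Genes of alternative activation, which accompany tissue repair, showed no common direction. Their list had a median of 0.02 and a mean of -0.02 over 17 members, 4 higher and 0 lower in all 3 pairs (camera adjusted p = 0.998). Mrc1, the mannose receptor, stood at 41.6 ± 2.89 CPM in NET-positive and 80.1 ± 44 CPM in NET-negative areas, and was higher in pair 1 and lower in the other pairs. Arg1, arginase 1, had 0 to 117 counts per library, and the count of 0 in the NET-positive library of pair 2 allows up to 0.0902 CPM. Anxa1, the pro-resolving annexin A1, and Il4ra, the interleukin 4 receptor, were higher in each pair at log2 fold changes of 0.53 ± 0.199 and 0.49 ± 0.236, and did not pass.

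Foam cell and Trem2-type macrophage genes had a median of 0.10 over 24 members, 7 higher and 1 lower in all 3 pairs (camera adjusted p = 0.519). Spp1, osteopontin, was among the most abundant transcripts, at 12520 ± 4810 CPM in NET-positive and 6077 ± 1130 CPM in NET-negative areas, and Trem2, a lipid receptor of foam cells, stood at 149 ± 51.3 against 88.3 ± 29.2 CPM (mean ± SD, n = 3). Genes of cholesterol efflux had a median of 0.02 over 19 members, 5 higher and 1 lower in all 3 pairs (adjusted p = 0.699). Abca1, the main exporter of cholesterol to apolipoprotein A-I, had a log2 fold change of 0.26 ± 0.158, and Nceh1, a cholesterol ester hydrolase, of 0.53 ± 0.213. Both were higher in all 3 pairs, Abcg2, another transporter of the family, was lower in all 3 at -2.69 ± 1.25 (4.37 ± 2.67 against 45.4 ± 53.6 CPM), and none passed. Glycolysis genes had a median of 0.27, with 6 of 19 members higher and 1 lower in all 3 pairs (adjusted p = 0.377). Pgam1 and Pkm, enzymes of lower glycolysis, were higher by 0.63 ± 0.203 and 0.64 ± 0.277 log2 units, and Pfkm, the muscle-type phosphofructokinase, was lower at -2.02 ± 0.798. NADPH oxidase and antioxidant genes had a median of 0.26 over 21 members, 5 higher and 2 lower in all 3 pairs (adjusted p = 0.625). Besides Ncf1, Cat, catalase, and Prdx1, a peroxiredoxin, were higher in each pair at 0.73 ± 0.228 and 0.47 ± 0.179, and Gpx4, which reduces lipid peroxides, was lower in each pair at -1.09 ± 0.387.

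Transcripts of neutrophils were scarce in the CD68-positive captures from both kinds of area. Capture was on CD68, so these counts do not measure how many neutrophils an area held. Padi4, the enzyme that citrullinates histones during NET release, had 0 to 3 counts per library, and Mpo, the granule enzyme myeloperoxidase, had 3 to 6, too few to test. The neutrophil list had 12 of 24 members measured, a median of -0.24, 0 members higher and 2 lower in all 3 pairs, and a camera adjusted p of 0.699. S100a8 stood at 3.01 ± 1.31 against 6.43 ± 3.62 CPM and was lower in each pair, S100a9 stood at 5.98 ± 3.87 against 5.51 ± 3.19 CPM, and Lcn2, lipocalin 2, at 70 ± 24.8 against 48.2 ± 29.3 CPM (mean ± SD, n = 3). None differed past the threshold.

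The other 22 lists tested did not pass. In 7 lists of metabolism and organelles (hypoxia response, nuclear and mitochondrial genes of respiration, ribosomal proteins, sterol synthesis, unfolded protein response, cholesterol efflux) the medians lay between -0.08 and 0.17. In 6 lists of defence and clearance (TLR and DNA sensing, complement, efferocytosis, migration, matrix-degrading proteases, MHC class II) they lay between -0.36 and 0.15. The class II gene H2-Ab1 stood at 111 ± 68.5 against 185 ± 48.3 CPM. In 4 lists of cell state (proliferation, apoptosis, resident-type macrophage genes, chondrocyte-like genes) they lay between -0.18 and 0.23. In 5 lists of other cells (T and NK, dendritic, cardiomyocyte, erythroid and platelet, B and plasma cells) they lay between -1.89 and 0.45, the lowest being that of B and plasma cells. Adjusted over the list alone, 0 members passed in each of the 35 lists other than the endothelial and the immediate early list, and 0 did over all genes. The lowest camera adjusted p of these 4 sets were 0.699, 0.667, 0.494 and 0.291. The camera direction was higher while the median was below 0 for resident-type macrophage genes and for TLR and DNA sensing, and lower while the median was above 0 for fibroblast and matrix genes.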

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

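The pairing was checked by the correlation of the deviations of same-coded libraries from their group means, which was 0.0501, 0.132 and 0.0569 for the 3 pairs, and not every library correlated best with its own partner, so the data give no firm pairing. With no replicate block edgeR called 0 genes higher and 0 lower and the endothelial list stayed the 1 list past the threshold, and of the 72 named genes and the 20 lists followed through the alternatives Ldlr alone turned (-0.48). The edgeR and limma-voom settings run all gave 0 genes in each direction, and the 9 fits without a pair or a library gave 0 too. DESeq2 gave 41 higher and 92 lower, and it called 18 of 72 named genes, F5 (adjusted p = 2.56e-19) and Eng (0.00486) among them. The cause of the gap between tools was not tested. For the endothelial list the call held in every camera setting with the preset correlation, without each pair or library too, and ended with an estimated correlation (0 lists lower) and with fry (0). Lists past the threshold as higher numbered 1 without a filter on low counts (immediate early and heat shock) and 2 at a mean count of at least 500 (also macrophage identity), a setting added after seeing the data, in which fewer genes were tested. Without a pair or a library, 0 to 4 lists were higher and 1 to 2 lower with the preset correlation, and without pair 2 there were 0 higher and 0 lower with an estimated correlation and with fry, both added after seeing the data. With 4 higher were the fits without pair 2, without the block and the NET-negative library of pair 2, and without the block and the NET-positive library of pair 3. Proliferation passed without pair 3, and with foam cell genes in the last of these fits. Without the NET-negative library of pair 2 the mitochondrially encoded and the erythroid and platelet lists passed. Without the block and the NET-positive library of pair 2 the cardiomyocyte list passed. Direction was kept throughout by 63 of 72 named genes and 8 of these 20 lists, and the other lists tested were not followed by direction. S100a9 turned with median-of-ratios size factors (-0.00832), library size alone (-0.0852), the replicate block with gene length correction (-0.0405) and DESeq2 (-0.00765), and Ldlr with limma-voom (-0.16). Library size alone also turned the list medians of smooth muscle (-0.0339), fibroblast (-0.0747), cholesterol efflux (-0.0716) and alternative activation (-0.063), the last also without a filter (-0.0491). A mean count of at least 50 turned the neutrophil list (0.00052) and one of at least 500 the fibroblast list (-0.0199). For these the cause was not tested. Library size alone moved the share of genes with a positive fold change from 50.4% to 44.3%, and their median to -0.0838.

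Over the fits without a pair or a library, log2 fold changes ranged from -0.11 to 0.41 for Cd68, -1.04 to 1.85 for Ldlr, -0.11 to 0.54 for Adgre1, -0.17 to 1.25 for Tnf, -1.13 to 0.15 for Ccl2, -2.92 to 0.97 for Arg1, -0.44 to 0.70 for S100a9, -0.57 to 0.66 for Acta2 and -1.50 to 0.15 for Selp. In all, 26 of 72 named genes moved by over 1.5 times in fold in at least 1 such fit. The fits without a library left out the block too, so their moves cannot be put down to the library alone. Of those that kept their direction and are not ranged in the report, Mrvi1 ranged from 1.58 to 2.83, Il1b 0.36 to 1.54, Mrc1 -1.35 to -0.32, Hspa1a 0.75 to 2.00, Cd14 0.20 to 1.60, Pfkm -2.60 to -1.06, Rtp4 -4.19 to -1.15, Ifit1 -3.65 to -1.63, Myocd 1.39 to 2.93, H2-Ab1 -1.54 to -0.41, Cxcl2 0.87 to 4.45, Ccl22 1.14 to 5.09 and Abcg2 -4.12 to -1.29. List medians ranged from -0.17 to 0.25 for inflammatory cytokines, -0.34 to 0.10 for inflammasome, -0.0628 to 0.314 for foam cell, -0.57 to 0.70 for smooth muscle, -0.26 to 0.36 for fibroblast, -0.689 to 0.0511 for neutrophil, -0.52 to 0.22 for chemokine, -0.369 to 0.0822 for alternative activation, -1.61 to 0.348 for erythroid, -0.174 to 0.297 for cholesterol efflux, -0.776 to 0.119 for T and NK cell and -3.16 to 1.20 for B and plasma cell genes, the last past the camera threshold without pair 3 with the preset correlation (adjusted p = 0.0344). That of endothelial markers ranged from -1.32 to -0.70, of immediate early genes from 0.133 to 0.527, of macrophage identity genes from 0.0823 to 0.37 and of lysosome genes from 0.0977 to 0.396. The median ranged from -1.08 to -0.0552 for dendritic cell markers and from -0.686 to -0.0694 for interferon-stimulated genes. For glycolysis genes it ranged from 0.211 to 0.351, and for NADPH oxidase and antioxidant genes from 0.0473 to 0.267. At a mean count of at least 500, edgeR recovered 51.5% of simulated 4-fold changes, against 21.8% over all genes. Genes of low count also had a wider spread between libraries, and depth itself was not varied.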

Other observations

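Tests of a lower share of all other cell types, of amplification losses, of reads from the neighbours of F5 and of the detected genes in pair 2 were chosen after the result was seen. A second list of 30 measured endothelial genes, with 0 members in the fixed lists, was lower in NET-positive areas too, with a median log2 fold change of -0.70, 13 members lower and 2 higher in all 3 pairs, and a camera adjusted p of 4.57e-05 over 2 lists with the preset correlation. That call was lost in the other tests, with an adjusted p = 0.217 with an estimated correlation and an adjusted p = 0.132 with fry. Both missed most lowered lists in the simulated data, so the loss cannot decide. Cd34, Clec14a and Calcrl, named after their values were seen, were lower in each pair at -1.45 ± 0.423, -1.60 ± 0.527 and -0.65 ± 0.206 (SE). A list of macrophages of the serous cavities, which carry F5 and Gata6, had a median of -0.27 over 13 measured genes (camera adjusted p = 0.0743), and Gata6 itself was lower in each pair at -1.22 ± 0.31.

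Chance cannot be judged from other splits of the libraries, because 3 against 3 make 10 splits, too few for a share under 0.05. For genes past the threshold the real split gave 0 and the highest other split 0, so that 10 of 10 were as large. For gene lists the real split gave 1 and the highest other split 6, and 9 of 10 splits gave at least as many. Under the block, 6 of the 10 splits part 1 pair and repeat that pair's own difference, the split with 6 lists among them. Of the 4 that part all 3 pairs, the real one gave 1 list and the others 0 to 4.

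Endothelial markers were lower in NET-positive areas, at a median of -1.05, a call lost with an estimated correlation (adjusted p = 0.971) and with fry (0.213). Both tests missed most lowered lists in the simulated data, so the loss cannot decide. The 12 members of the fixed list with a mean count of at least 500 had a median of -1.14, so low-count members alone do not carry the difference. These counts were taken after amplification and do not show how many molecules there were. A loss of transcripts during amplification therefore stays open. A shared fall of all other cell types in the NET-positive captures is argued against by the medians of pairs 1, 2 and 3. Smooth muscle stood at 0.791, -1.28 and 0.868, fibroblast at 0.316, 0.27 and -0.445, and T and NK cell markers at -0.261, -0.198 and 0.472. In each pair some of these lay above 0. The fibroblast median lay above the endothelial one by at least 0.658 in each pair, but the smooth muscle median did so in 2 of 3 pairs only. A lower share of some of these cell types stays open. More endothelial cells in the NET-negative captures stay among the explanations, although capture was on CD68. Eng and Ptprb stood at 204 and 273 CPM there. The second list went the same way (-0.704). It passed the camera threshold with the preset correlation but not with an estimated one (adjusted p = 0.217) or fry (0.132). Its genes mark the same cell type in the same libraries and could fall under other causes too, so it cannot decide between explanations. A change within the cells themselves in areas with NETs was not tested.

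F5 was higher in each NET-positive library. A larger share of serous-cavity-type macrophages was not seen in the list median of -0.274, with -0.0752, -0.888 and -0.0856 in the pairs. It stays open, because several members were measured loosely, with SE of 2.59 for Saa3, 3.69 for Slpi and 2.15 for Vsig4. Gata6 itself was lower in each pair. Reads spilling over from the neighbouring genes Selp and Slc19a2 are argued against, because the ratio of the F5 count to their summed counts was 3.19 times as high in the lowest NET-positive as in the highest NET-negative library. An earlier bound, neighbours below 0.1 of the F5 count in each NET-positive library, was met in 1 of 3 and was replaced by this one. A difference between areas with and without NETs may also stay among the explanations, untested on other samples.

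Both libraries of pair 2 had fewer detected genes than the others. Fewer reads are argued against, because their total counts were 35316480 and 37613102, the lower of them 1.13 times the mean of the other 4, which had 27247261 to 35624397. Transcripts lost at random before or during amplification stay open: at least 27 genes with a mean count of 200 or more elsewhere had a count of 0 in each library of pair 2, against at most 15 in the other 4, but this restates the lower number of detected genes and does not part loss from absence in the captured cells. No biological explanation was tested.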
